A study of Mus musculus with 4 samples.

How the data were processed

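Brain cortex of male SAMP8 mice given TCQA or water was profiled on Clariom S mouse arrays, with 2 arrays per group. Per the labels' protocols, the mice were housed singly from 7 months of age for 4 months, treated from 11 months of age for 1 month, and 100 ng of RNA was amplified and labelled with the WT PLUS kit. The deposited values are log2 signals, 1 per probe set, and per the labels' protocols the authors made them with the SST-RMA algorithm in the Transcriptome Analysis Console (version 4.0.2). As an algorithm, it corrects for probe sequence, normalizes the arrays to a common distribution and summarizes the probes of a set. A probe set therefore has a relative level that can be compared between arrays, and its level was not set against that of another. The labels' protocols also name limma, a one-way comparison with empirical Bayes moderation, a detection cutoff of 0.05, a positive over negative area under the curve of at least 0.7, and a criterion of p under 0.05 with a fold change over 2. The genome build of the annotation is not given in the sources used here, so no coordinates are given.

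The table held 28846 probe sets, of which 6640 were control probe sets. The other 22206 entered the tests. Through the platform annotation, with symbols updated by the gene table given with the data, 19572 of them had 1 symbol, 0 had several, and 2634 were not named here and were only counted. Detection calls were not used here, so dim genes stayed in the tests. In place of depth, the signal over background was read from the controls: the median negative control probe set lay at 7.17 to 7.32 on the 4 arrays, near the gene medians of 7.12 to 7.17, and the median positive control at 10.65 to 10.77. The 23 background probe sets had lower medians, of 5.84 to 6.00. The negative controls spread widely, with upper quartiles of 8.55 to 8.75, so their median marks dim genes and is not a floor of the signal. The area under the curve of positive over negative controls was 0.775 and 0.776 for the TCQA arrays and 0.768 and 0.779 for the control arrays. On each array the median gene lay under the median negative control, and differences among dim genes are less certain. The number of arrays limits the precision, and the median standard error of a log2 difference was 0.20.

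Groups were taken from the sample titles. The labels do not say that the arrays of a group came from separate mice, so the p-values measure the spread between these samples, which may be partly technical. The groups were compared with limma 3.58.1 in R 4.3.3 on the deposited log2 values, with lmFit and eBayes, two-sided, as TCQA minus control, and with Benjamini-Hochberg adjustment over all 22206 probe sets. The fit had 2 residual degrees of freedom and a prior of 4.23. The depositors' criterion was counted in the same fit. The 6640 control probe sets were fitted separately in the same way. The median log2 difference over all genes was 0.01.

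Before the data were examined, 44 gene lists of cell types, brain regions, synaptic, signalling, stress, immune and metabolic genes were written from general knowledge, and the tests, the alternatives and the rule for naming genes were set. The lists had 5 to 75 measured genes and 1071 different symbols, of which 57 were in more than 1 list, and 131 listed symbols had no named probe set here. They were tested with limma's camera at a preset inter-gene correlation of 0.01 and adjusted over the 44 lists, after keeping the brightest probe set of each symbol, which left 19505 symbols. Camera asks whether the genes of a list rank higher or lower than the other genes. Camera with an estimated correlation and fry, which asks whether the genes of a list move one way on balance, were alternatives. With an estimated correlation camera rests on the 2 residual degrees of freedom, as does fry, so a list could hardly pass either here. For each list the genes that passed limma when adjusted over the list alone were counted beside those adjusted over all genes.

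The rule for named genes took up to 12 per direction: genes past the adjusted threshold first, then those past the depositors' criterion by size of change, then those with the smallest unadjusted p. A named gene had both TCQA arrays on the same side of both control arrays, a mean in its higher group at or above the median of all genes (7.14), and no predicted, olfactory, vomeronasal or taste receptor symbol. All 12 higher genes and 11 of the lower genes came from the criterion, and 1 from the unadjusted p. Up to 4 members of each list with the smallest p were allowed as examples, and Ttr, Drd2, Prox1 and Tcf7l2 always. Hbb-bs, Xist and Ddx3y, allowed by the same rule, were not analysed here.

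The procedure was tested on simulated data for this comparison, with 22206 genes in 20 simulations. Of genes changed by 1.5 on the log2 scale 96.1% met the criterion and 56.2% the adjusted threshold, and of genes changed by 3, 99.95% and 97.25%. On average 126.75 unchanged genes met the criterion in a simulation, and 0 of 20 simulations called a list. The spread of each simulated gene was drawn from the fitted prior and not from its own values, so 126.75 is not a chance level for the data. The simulated genes varied independently of each other, so the list result does not cover genes that move together, as those of a list may. The alternatives were a variance prior with intensity trend and robust estimation, quantile normalization, median centring, filters at the median and the 25th percentile of signal, the replicate number as a block, each array left out in turn, the methods' test without moderation, an adjusted p under 0.1, a fold change over 1.5, non-overlapping arrays, camera with an estimated correlation, camera on ranks, and fry.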

Results

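Gene expression was measured in the brain cortex of male SAMP8 mice, an inbred strain that ages early and develops learning and memory deficits. The treated group received TCQA, a compound known here by its abbreviation, by mouth at 5 mg/kg every day for 1 month from 11 months of age. The control group received purified water. Each group had 2 arrays, and the values were log2 signals on a microarray that measures the well-annotated mouse genes. The 4 arrays were close to each other, with correlations across genes of 0.991 to 0.993. The TCQA pair had a standard deviation of log2 differences of 0.397 and the control pair one of 0.375, against 0.377 to 0.409 for pairs of arrays from different groups. Array medians over the 22206 gene probe sets lay between 7.12 and 7.17. The number of arrays limits the precision of every value given here.

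The comparison of the groups asked which cortical genes differed after 1 month of TCQA. Immediate early genes, which neurons switch on rapidly when they are active, were lower with TCQA: 30 of the 32 measured had a lower mean, and 9 were over 2-fold lower at an unadjusted p under 0.05. Control replicate 1 was the highest array for 27 of the 32, and without it the list median went from -0.37 to -0.15. Interferon response genes were higher in 28 of 32, mostly through 1 of the TCQA arrays, and genes of meningeal fibroblasts were higher in 18 of 20, mostly through a low level in 1 of the control arrays. Outside these groups Calb2, the calcium-binding protein calretinin, was 2.83-fold higher. Trh, which encodes the precursor of thyrotropin-releasing hormone, was higher too, from a control level under the median of the negative control probe sets. No single gene passed limma with Benjamini-Hochberg adjustment over all genes (0 of 22206, smallest adjusted p = 0.698), while 1386 had an unadjusted p under 0.05, where 1110.3 would be expected with no effect. In a separate fit of the control probe sets 6.65% of the negative controls (347 of 5222) had an unadjusted p under 0.05, a share no smaller than that of the genes. Among the positive controls of that fit the share was smaller than that of the genes, at 2.95% (39 of 1324).

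Among the immediate early genes the activity-dependent transcription factors Npas4, Fos, Junb and Nr4a1 were all lower with TCQA. Npas4 had a mean log2 signal of 6.58 ± 0.36 with TCQA and 8.72 ± 0.93 in control (SD, n = 2 each), a difference of -2.13 (SE 0.43) with a TCQA level under the median of the negative control probe sets. The difference was -1.68 for Junb (SE 0.31), -1.60 for Nr4a1 (SE 0.36) and -1.32 for Fos (SE 0.35). Dusp1, a phosphatase that turns off MAP kinases, was at 12.34 ± 0.26 with TCQA and 14.41 ± 0.73 in control (SD, n = 2 each), a 4.18-fold lower level. Btg2, an antiproliferative early gene, differed by -2.45 (SE 0.69), and Ccn1, a secreted matrix protein, by -2.27 (SE 0.44). Arc, which regulates AMPA receptor traffic at synapses, differed by -1.17 (SE 0.39). Ier2 differed by -1.06 (SE 0.17), with both groups below the median of the negative control probe sets. The list median was -0.37 (camera adjusted p = 1.24e-10, and adjusted p = 0.774 with an estimated correlation). Of its 32 genes, 8 passed when adjusted over the list alone and 0 when adjusted over all genes. The highest array was control replicate 1 for 27 of the 32 genes, and without that array the list median was -0.15 (camera adjusted p = 1.04e-05, and adjusted p = 0.984 with an estimated correlation), the Btg2 difference -1.27, the Nr4a1 difference -1.06, the Fos difference -0.79 and the Arc difference -0.66. Without control replicate 2 the list median was -0.60 (camera adjusted p = 6.41e-18).

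**Figure D1:**
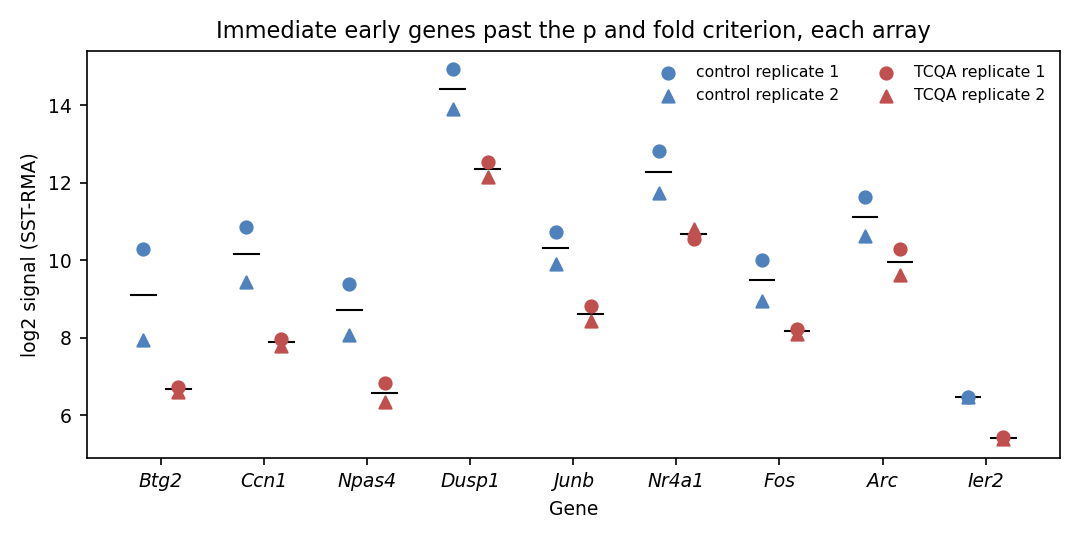
Log2 signal (vertical axis) of the 9 immediate early genes that were over 2-fold lower with TCQA at an unadjusted p under 0.05, with 1 point per array and a line at each group mean. In each of the 9 genes both TCQA arrays lay below both control arrays, and control replicate 1 was clearly above control replicate 2 in most, as for Btg2 at 10.30 and 7.93.

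The criterion that the depositors describe, an unadjusted p under 0.05 with a fold change over 2, was met by 83 probe sets, 45 of them higher and 38 lower with TCQA. Of these 83, 42 were below the median signal of all genes in both groups. The 83 were among 22206 gene probe sets, and the same criterion was met by 216 of 5222 negative and 17 of 1324 positive control probe sets. In simulations of this comparison 126.75 unchanged genes met it on average. Dividing the 4 arrays into pairs in the other ways gave fewer, 86 and 55. The spread of a simulated gene was drawn from the fitted prior and not from its own values, so 126.75 is not a chance level for the 83. The largest difference among the higher genes that the naming rule took was that of Trh, with a mean log2 signal of 7.72 ± 0.24 with TCQA and 5.57 ± 0.11 in control (SD, n = 2 each), a difference of 2.14 (95% confidence interval 1.65 to 2.63, limma adjusted p = 0.698) whose size is uncertain because the control level is dim. Cxcl13, a chemokine that attracts B cells, differed by 2.04 (SE 0.56), but by 1.15 without control replicate 1. Zic1, a transcription factor of thalamic and cerebellar neurons and of the meninges, differed by 1.89 (SE 0.67). Its control arrays differed, at a mean of 9.61 ± 1.57 (SD, n = 2), and the difference was 0.78 without control replicate 1 and 3.0 without control replicate 2. Ogn, a small proteoglycan of connective tissue, was 2.83-fold higher. Hpca, the calcium sensor hippocalcin, was at 16.67 ± 0.18 with TCQA and 15.44 ± 0.07 in control (SD, n = 2 each), a 2.34-fold difference. Calb2 was at 11.07 ± 0.27 and 9.56 ± 0.20 (SD, n = 2 each). Cbln1, a secreted synapse organiser, differed by 1.15 (SE 0.24), Pcsk1n, an inhibitor of a prohormone convertase, by 1.15 (SE 0.24), and Slc18a2, the vesicular monoamine transporter, by 1.13 (SE 0.24). Uprt differed by 1.39 (SE 0.18), Rab2b by 1.24 (SE 0.19) and the astrocyte enzyme gene Etnppl by 1.22 (SE 0.30).

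Lower genes outside the immediate early list included Lingo2, a neuronal membrane protein, which differed by -1.46 (SE 0.28). Ckmt1, the mitochondrial creatine kinase, was at 11.68 ± 0.15 with TCQA and 12.77 ± 0.03 in control (SD, n = 2 each), a 2.12-fold lower level. Dnah6, an axonemal dynein chain, differed by -1.11 (SE 0.28). Eefsec, the elongation factor for selenocysteine, differed by -0.93 (SE 0.18), under 2-fold. For each of the named genes other than Trh the limma adjusted p was 0.787 or higher. The lower group of Trh, Ogn, Slc18a2, Btg2, Npas4 and Dnah6 lay under the median of the negative control probe sets, as did, among list members, that of Fgf2, Cd55 and Apaf1 and both groups of Matn4, Myh11, Grp, Dll1, Nfe2l2, Fdps and Psen2. The size of these differences is less certain. Without empirical Bayes moderation 25 probe sets met the criterion, and leaving out 1 array gave 218 without TCQA replicate 1, 291 without TCQA replicate 2, 160 without control replicate 1 and 231 without control replicate 2.

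Interferon response genes, which are induced in antiviral and innate immune signalling, had a median difference of 0.44, with 28 of 32 higher (camera adjusted p = 1.51e-06, and adjusted p = 0.774 with an estimated correlation). At an unadjusted p under 0.05, 6 were higher and 0 lower. None passed when adjusted over the list alone or over all genes (0 by limma each way). Ddx58, the cytoplasmic RNA sensor RIG-I, was at 7.57 ± 0.07 with TCQA and 6.66 ± 0.08 in control (SD, n = 2 each), a difference of 0.91. The guanylate-binding protein gene Gbp2 differed by 0.81 (SE 0.19), the class I histocompatibility gene H2-K1 by 0.53 (SE 0.18) and Ifit2 by 0.51 (SE 0.19). Both groups of Gbp2 and the control group of Ddx58 and Ifit2 lay under the median of the negative control probe sets. Much of the list was dim, with 10 of the 32 genes at or above the median signal. In these the list median was 0.47, with 9 higher (camera adjusted p = 0.00491). The highest array was TCQA replicate 1 for 28 of the 32 genes. Without that array the list median was 0.03 (camera adjusted p = 0.376), and without TCQA replicate 2 it was 0.71 (camera adjusted p = 4.8e-20).

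Genes of disease-associated microglia and reactive astrocytes, the states these cells take in neurodegeneration and injury, were higher in 27 of 32, with a median of 0.21 (camera adjusted p = 0.00118, and adjusted p = 0.774 with an estimated correlation). At an unadjusted p under 0.05, 4 were higher, and 0 passed limma when adjusted over the list alone or over all genes. The acute-phase gene Serpina3n was at 11.11 ± 0.53 with TCQA and 10.24 ± 0.26 in control (SD, n = 2 each), a difference of 0.87 that was 0.49 without TCQA replicate 1. The chemokine Ccl6 differed by 0.64 (SE 0.19), the intermediate filament Vim by 0.45 (SE 0.18) and the oncostatin M receptor Osmr by 0.43 (SE 0.17), with both groups of Ccl6 and Osmr under the median of the negative control probe sets. In the 16 of the 32 genes at or above the median signal the list median was 0.14 (camera adjusted p = 0.0351). The list passed camera without each array in turn, with adjusted p from 0.005 to 0.0244, and its median was 0.14 without TCQA replicate 1. Microglia markers had a median of 0.08 (camera adjusted p = 0.271), with the receptor P2ry13 0.57 higher (0.36 without TCQA replicate 1), and astrocyte markers a median of 0.15 (camera adjusted p = 0.215).

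Meningeal fibroblast and collagen genes had a median difference of 0.41, with 18 of 20 higher (camera adjusted p = 0.000453, and adjusted p = 0.774 with an estimated correlation). Besides Ogn, the transporter genes Slc6a20a and Slc6a13 differed by 0.70 (SE 0.19) and 0.63 (SE 0.17), and the matrix Gla protein gene Mgp by 0.79 (SE 0.28). Without control replicate 1 Mgp differed by 0.43 and Slc6a13 by 0.66. Control replicate 1 was the lowest array for 16 of the 20 genes. Without it the list median was -0.04 (camera adjusted p = 0.522), and without control replicate 2 it was 0.68 (camera adjusted p = 4.71e-11). Choroid plexus markers moved with this array too. Ttr, the transthyretin gene that the choroid plexus transcribes at a very high level, had log2 signals of 12.23 and 14.97 with TCQA and of 7.49 and 16.42 in control. The choroid plexus list had a median of -0.06, a mean of 0.12 and a camera adjusted p of 0.939.

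**Figure D2:**
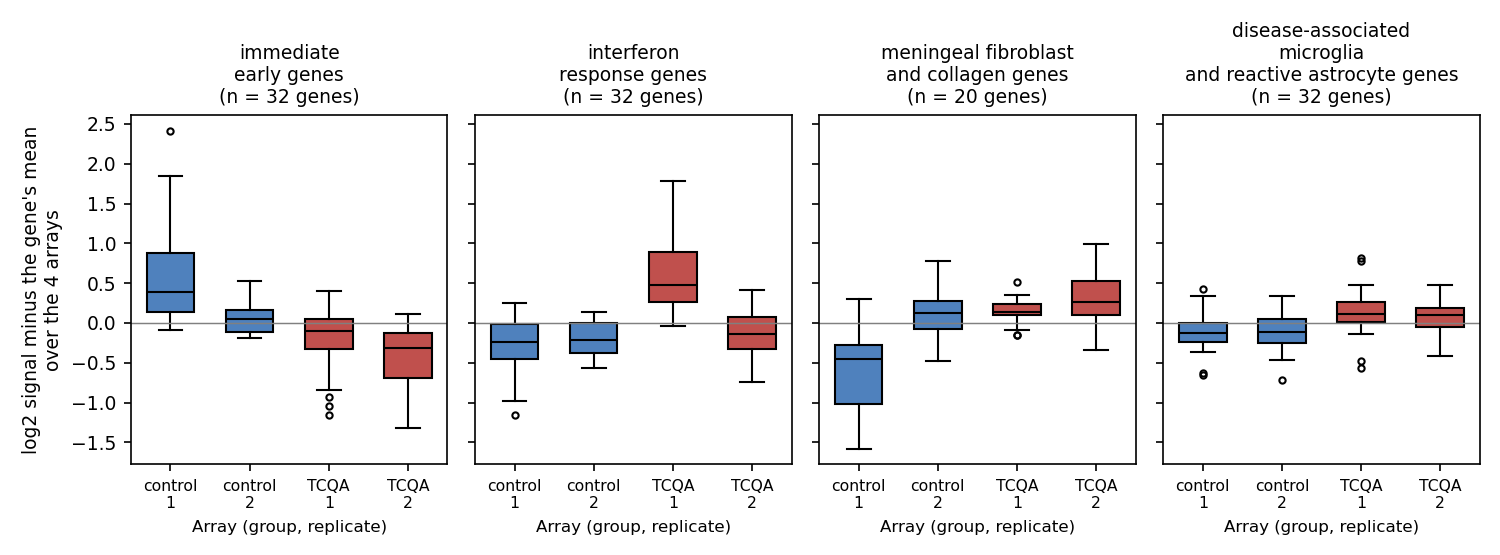
Log2 signal of each gene minus its mean over the 4 arrays (vertical axis), by array, for the 4 gene lists past the camera threshold, as boxes over genes with the median, the quartiles and whiskers to 1.5 times the box height. Control replicate 1 is highest for the immediate early genes and lowest for the meningeal genes, and TCQA replicate 1 is highest for the interferon genes, in which it led for 28 of 32.

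Of the other neuronal lists, none passed camera with adjustment over the 44 lists, where 4 passed and 15 had an unadjusted p under 0.05. With fry, or with an estimated correlation in camera, 0 of the 44 passed. Glutamate receptor and postsynaptic genes had a median of -0.12 (camera adjusted p = 0.0633). The scaffold genes Shank1, Shank2 and Dlgap2 and the adhesion gene Nlgn2 each differed by between -0.63 and -0.70, with both TCQA arrays below both control arrays. They were the 4 members with the smallest p, and 36.6% of all gene probe sets had non-overlapping arrays, against 33.3% by chance. Excitatory neuron markers had a median of -0.16 (camera adjusted p = 0.11), with Nrgn, a calmodulin-binding protein of dendritic spines, at -0.70 (SE 0.23), Neurod2 at -0.50 (SE 0.20) and the upper-layer gene Cux2 at -0.48 (SE 0.19). Of its 19 genes 6 were higher, among them the glutamate transporter gene Slc17a6 at 0.88 (SE 0.42), which is also a thalamic marker and differed by 0.21 without TCQA replicate 2 and 1.56 without TCQA replicate 1. Inhibitory neuron markers had a median of 0.21 (camera adjusted p = 0.0933). Besides Calb2, Dlx6 differed by 0.86 (SE 0.22) and Adarb2 by 0.64 (SE 0.19), while the potassium channel gene Kcnc1 differed by -0.58 (SE 0.18). Presynaptic genes went both ways, with Snap25 at 0.62 (SE 0.18) and the active zone gene Bsn at -0.86 (SE 0.19), and a list median of -0.06 (camera adjusted p = 0.683). GABA receptor genes had a median of 0.16 (camera adjusted p = 0.586).

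Calcium channel and binding genes had a median of -0.10, a mean of 0.04 and a camera adjusted p of 0.809. The calcium sensors Hpca and Vsnl1 were higher, Vsnl1 by 0.83 (SE 0.18), and the channel gene Cacna1a differed by -0.61 (SE 0.17). Adjusted over the list alone, 3 calcium genes, 2 glucocorticoid-responsive genes and 1 gene each of the thalamic, hypothalamic, inhibitory and meningeal lists passed, against 0 when adjusted over all genes. Beyond these and the immediate early list, 0 genes of any list passed adjusted over the list alone. The lists share genes: Calb2 was counted in the inhibitory, thalamic and calcium lists. Dusp1 was counted in both the glucocorticoid-responsive and the immediate early list. Adjustment over a list alone makes no correction over the 44 lists. Potassium and sodium channel genes had a median of -0.07 (camera adjusted p = 0.586), with the sodium-activated channel gene Kcnt1 at -0.60 (SE 0.20). Monoamine and acetylcholine genes had a median of 0.06 (camera adjusted p = 0.236), with the serotonin receptor gene Htr1b at 0.82 (SE 0.29, and 0.50 without control replicate 1) and Maob, which degrades amines, at 0.53 (SE 0.19). Neurotrophin and CREB signalling genes had a median of 0.01, a mean of -0.01 and a camera adjusted p of 0.793, with Fgf2 at 0.56 (SE 0.18).

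Markers of neighbouring brain regions were also read. Thalamic neuron markers had a median of 0.17 (camera adjusted p = 0.0608), and Calb2 and Zic1 were its members past the criterion. Tcf7l2, a thalamic marker, had log2 signals of 9.71 and 11.54 with TCQA and of 9.74 and 10.18 in control. Hypothalamic and neuropeptide genes, which include Trh, had a median of 0.04 (camera adjusted p = 0.158), and TCQA replicate 2 was the highest array for 17 of the 28 and the lowest for 8. Striatal neuron markers had a median of 0.02 (camera adjusted p = 0.745), with TCQA replicate 2 highest for 15 of the 20 and Drd2 at -0.07 (SE 0.24). Hippocampal neuron markers had a median of 0.03, a mean of -0.01 and a camera adjusted p of 0.795. Prox1 differed by 0.04 (SE 0.18) and the peptide gene Grp by -0.53 (SE 0.17).

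Endothelial markers had a median of 0.17, with 15 of 20 higher (camera adjusted p = 0.0633). The glucose transporter gene Slc2a1 of the blood-brain barrier differed by 0.57 (SE 0.19) and the organic anion transporter gene Slco1a4 by 0.47 (SE 0.18). Pericyte and smooth muscle markers had a median of 0.05 (camera adjusted p = 0.375), with Myh11 at 0.53 (SE 0.19). Oligodendrocyte and myelin genes had a median of -0.02, a mean of 0.06 and a camera adjusted p of 0.707. The glial gap junction gene Gjc3 was 2.01-fold higher, and the protease gene Klk6 differed by -0.53 (SE 0.17). Oligodendrocyte precursor markers had a median of 0.05 (camera adjusted p = 0.438), with Matn4 at 0.53 (SE 0.17). Red blood cell genes had a median of -0.02 (camera adjusted p = 0.63), with the haem synthesis gene Fech at -0.55 (SE 0.18). T cell, B cell and neutrophil markers had a median of 0.05 (camera adjusted p = 0.882). Neural progenitor and neurogenesis genes had a median of 0.01 (camera adjusted p = 0.586), with the fatty acid binding protein gene Fabp7 at 0.76 (SE 0.30, and 0.46 without TCQA replicate 1 or 0.43 without control replicate 2) and the Notch ligand gene Dll1 at -0.48 (SE 0.18). Wnt signalling genes had a median of 0.08 (camera adjusted p = 0.793), with the Wnt antagonist Sfrp1 at 0.66 (SE 0.17), the 1 higher member at an unadjusted p under 0.05 beside 2 lower ones.

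Glucocorticoid-responsive genes had a median of 0.11 (camera adjusted p = 0.0899), with Pdk4, which limits glucose oxidation, at 0.96 (SE 0.18) and the receptor co-chaperone Fkbp5 at 0.50 (SE 0.18), while Dusp1, also in this list, was lower. NRF2 antioxidant genes had a median of 0.10 (camera adjusted p = 0.21), in which the cystine transporter gene Slc7a11 differed by 0.69 (SE 0.19), Gstp1 by 0.75 (SE 0.24, and 0.47 without control replicate 2) and the catalase gene Cat by 0.58 (SE 0.22, and 0.33 without TCQA replicate 2). At an unadjusted p under 0.05, 4 NRF2 genes were higher and 1 lower. Nfe2l2, which encodes NRF2 itself, differed by 0.49 (SE 0.18) at a dim signal of 5.28 with TCQA. Cytokine and NF-kB inflammatory genes had a median of 0.12 (camera adjusted p = 0.0633), with Casp1 at 0.78 (SE 0.23) and the alarmin gene Il33 at 0.56 (SE 0.22, and 0.32 without TCQA replicate 2). Complement genes had a median of 0.10 (camera adjusted p = 0.11), with the complement inhibitor gene Cd55 at 1.09 (SE 0.34, and 0.67 without TCQA replicate 1). Heat shock and chaperone genes had a median of 0.19 (camera adjusted p = 0.0633). Unfolded protein response genes had a median of 0.15 (camera adjusted p = 0.0836), with the transcription factor gene Xbp1 at 0.71 (SE 0.22). Apoptosis genes had a median of 0.09 (camera adjusted p = 0.0837), in which the anti-apoptotic Bcl2 and the pro-apoptotic Apaf1 differed by 0.72 (SE 0.18) and 0.66 (SE 0.19).

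Oxidative phosphorylation genes, the longest list, had 39 of 75 higher and 36 lower, a median of 0.01 and a camera adjusted p of 0.801. Uqcr10 of complex III differed by -0.60 (SE 0.17) and Sdha of complex II by 0.55 (SE 0.21, and 0.34 without control replicate 1). Lipid and cholesterol synthesis genes were higher in 15 of 22, with a median of 0.08 (camera adjusted p = 0.337). The cholesterol synthesis genes Hmgcs1 and Fdps were at 0.41 (SE 0.17) and 0.42 (SE 0.18), and the fatty acid synthesis genes Fasn and Acly at -0.52 (SE 0.17) and -0.46 (SE 0.18). Glycolysis genes had a median of 0.04 (camera adjusted p = 0.643). Ribosomal protein genes had a median of -0.04 (camera adjusted p = 0.643), proteasome genes -0.02 (camera adjusted p = 0.707) and lysosome and autophagy genes -0.03 (camera adjusted p = 0.337). Amyloid and tau genes had a median of -0.05 (camera adjusted p = 0.657), with the presenilin gene Psen2 at 0.48 (SE 0.18). Circadian clock genes had a median of 0.07 (camera adjusted p = 0.643), with Per2 at 0.36 (SE 0.17), and cell cycle and senescence genes a median of 0.02 (camera adjusted p = 0.745).

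**Figure D3:**
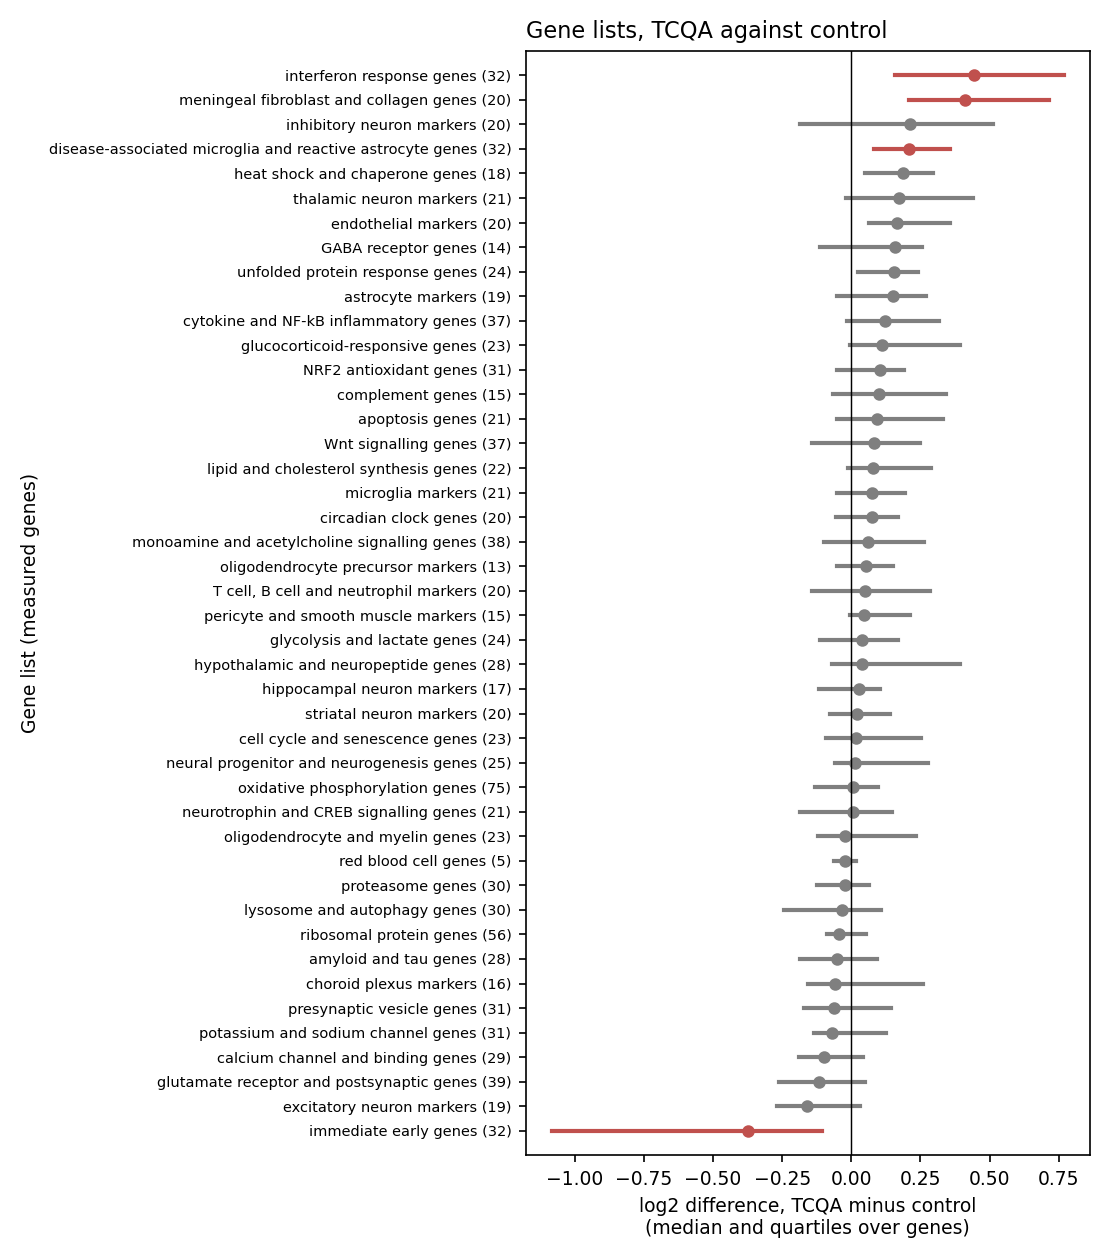
Log2 difference of TCQA minus control (horizontal axis) for the 44 gene lists (vertical axis, with the number of measured genes), as the median over genes with a bar between the quartiles. The 4 lists past the camera threshold are red, with the immediate early genes at a median of -0.37 and the interferon genes at 0.44.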

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

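1 alternative was added after the results were seen, the immediate early list without control replicate 1 at an estimated correlation, where its median was -0.15 and its camera adjusted p 0.984. No gene passed limma's adjusted threshold under any alternative (0, with 1386 at an unadjusted p under 0.05) except without TCQA replicate 1, which gave 4, so that leaving out each array gave 0 to 4. The smallest adjusted p was 0.0598 with trend and robust estimation. The 83 probe sets past the depositors' criterion became 759 at a fold change over 1.5, 36 with a filter at the median signal and 25 without moderation. The lower numbers follow in part from fewer genes tested and fewer degrees of freedom. They were 80 to 83 with trend and robust estimation and with both other normalizations, and 57 with the filter at the 25th percentile. Leaving out each array gave 160 to 291, of which 54 to 59 were among the 83, and an array left alone in its group is then assumed to vary like the other group. The labels do not say that the replicate numbers pair mice, so they were not taken as pairs. Same-numbered arrays deviated together with a correlation of 0.05 over all genes, but some lists moved with the number. Replicate 1 was above replicate 2 for 28 of 32 immediate early genes in control and 26 with TCQA. For striatal markers it was above in 4 of 20 in control and 1 with TCQA. With the replicate number as a block the count was 92, and 6 lists passed in place of 4.

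The 4 lists past camera became 0 with an estimated correlation and 0 with fry, at unchanged medians of -0.37 for the immediate early, 0.44 for the interferon, 0.41 for the meningeal and 0.21 for the disease-associated microglia and reactive astrocyte list. With an estimated correlation, camera rests on the 2 residual degrees of freedom of the fit and could hardly pass a list over 44. It decides little either way here. The test of fry rests on the same 2 degrees of freedom, and its smallest unadjusted p was 0.0114, so it decides little too. The 4 lists became 11 with an intensity trend alone, as robust estimation did not enter the list test, and 7 with the filter at the 25th percentile. In both the 4 were included. Leaving out each array gave 5 to 11 lists, with 11 without TCQA replicate 1 and 9 without control replicate 2. The medians then ranged from -0.60 to -0.15 for the immediate early, 0.028 to 0.71 for the interferon, -0.038 to 0.68 for the meningeal and 0.14 to 0.25 for the disease-associated microglia list. Among these fits the meningeal list was negative only without control replicate 1, and the interferon list was past its threshold in all but the one without TCQA replicate 1.

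Of the 24 genes named by the rule, 0 reversed under the alternatives, which covered all 24 except that the filter at the median signal left 21. The rule took only genes with non-overlapping arrays, so leaving out 1 array could not reverse them. Trend and robust estimation, the filters, the block and the test without moderation leave the difference itself unchanged. Only quantile normalization and median centring could have reversed a gene. An unadjusted p under 0.05 was kept by 22 to 24 without each array, with Zic1 and Arc lost without TCQA replicate 2 and Arc without control replicate 1, by 23 with trend and robust estimation (Zic1 lost) and by 7 without moderation. Of 59 list examples named with such a p, 24 to 31 kept it without each array and 0 reversed. Their arrays did not overlap either, so leaving out 1 array could not reverse them. It held without each array in turn for 11, Bcl2, Bsn, Cacna1a, Ddx58, Dlx6, Gbp2, Gjc3, Ier2, Pdk4, Sfrp1 and Vsnl1. Among genes that had not passed, Ttr was at -2.82 without control replicate 1 and 6.11 without control replicate 2, and Prox1 at 0.13 and -0.045. Without TCQA replicate 1 and 2 respectively, Pmch was at 4.66 and -0.24, Tcf7l2 at 1.58 and -0.25, and Drd2 at 0.21 and -0.35. Signal over background limits the dim genes: 42 of the 83 were below the median signal in both groups.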

Other observations

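The leave-one-out fits were planned, while their use to weigh a pattern, the estimated correlation without control replicate 1, the counts by array, the marker comparisons and the splits of the arrays were chosen after the results had been seen. The genes named in this part beyond the rule were also chosen after their values were seen. Within the immediate early list the lower level did not extend to every activity gene. Fosb differed by -0.02 (SE 0.20), Homer1 by -0.14 (SE 0.19), Bdnf, the brain-derived neurotrophic factor gene, by -0.11 (SE 0.20), Nptx2 by 0.00 (SE 0.18) and the clock gene Per1 by -0.02 (SE 0.18), beside -2.13 for Npas4 and -1.32 for Fos. Leaving out each array in turn put these 5 genes between -0.30 and 0.11. Egr1 differed by -0.33 (SE 0.24), by -0.05 without control replicate 1 and by -0.61 without control replicate 2.

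A few hormone and receptor genes stood out in TCQA replicate 2. Pmch, the melanin-concentrating hormone gene of lateral hypothalamic neurons, had a log2 signal of 10.32 there and of 5.37 to 5.96, under the negative control median, on the other arrays. Gabrq, a GABA receptor subunit gene, was at 8.49 against 5.00 to 5.82, and Gh, the growth hormone gene, at 8.31 against 4.60 to 5.40. With TCQA replicate 1 left out, these 3 genes and 1 probe set not named here were the 4 past limma's adjusted threshold, Pmch with an adjusted p of 0.0048. Tcf7l2 stood at 11.54 against 9.71 to 10.18, and 15 of 20 striatal markers were highest on this array. The hypothalamic and neuropeptide list was split on it, with 17 of 28 genes highest and 8 lowest there. Without this array Slc17a6 differed by 0.21 and Tcf7l2 by -0.25 in place of 0.88 and 0.67, while Trh differed by 1.97. More tissue from neighbouring brain regions on this array stays open for the genes that it alone carried, and the difference of Trh did not rest on it alone.

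The immediate early genes were lower with TCQA, with a list median of -0.37 (camera adjusted p = 1.24e-10). Control replicate 1 held the highest value for 27 of 32, and whether it is the whole source stays open. Without it the median was -0.15, less than the median gap of 0.24 between the TCQA arrays. That array stood apart in other lists too, highest for 10 of 19 excitatory neuron markers and lowest for 16 of 20 meningeal genes. Differences between mice whatever their group remain open too, as the list also passed when both arrays numbered 1 were set against both numbered 2 (camera adjusted p = 3.26e-05), and not in the remaining split (adjusted p = 0.483). These genes respond within minutes to handling, so the moments before tissue collection may have differed between mice. An effect of TCQA remains among the open explanations, as untested.

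As a list, the interferon genes may be higher in TCQA replicate 1 alone: without it their median was 0.028 (camera adjusted p = 0.376). On that array Ifit3 was at 10.85 against 7.90 to 8.82 on the others, and Ifitm3 at 10.94 against 8.83 to 8.92. Not every member followed it, since Ddx58 was 0.87 and Gbp2 0.76 higher without that array. Both were among the members with the smallest p and had non-overlapping arrays, so leaving out 1 array could not reverse them. Of the 32 genes 17 were higher and 15 lower without that array, with Oasl2 at -0.35. A larger share of microglia on that array is argued against, since the microglia markers there stood -0.027 from the mean of the other arrays at their median, with an upper quartile of 0.32, against 0.64 for the interferon list. The interferon list also passed in both other divisions of the arrays (camera adjusted p = 8.61e-05 and 2.32e-05). In each of them TCQA replicate 1 stood with a control array. An interferon response in 1 mouse, with or without TCQA as its source, stays open as an untested hypothesis.

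The meningeal genes may be higher only because control replicate 1 was low, as their median was -0.038 without it (camera adjusted p = 0.522). Less choroid plexus and meninges in the tissue of that array is a candidate explanation, since 11 of 16 choroid plexus markers were lowest there (exact one-sided binomial p = 0.000285 against a chance of 1 in 4, over genes that are not independent). Slc13a4 stood at 5.28 there and at 7.18 to 7.58 on the other arrays, and Ttr at 7.49 against 12.23 to 16.42. Control replicate 2 was in turn the highest array for 10 of the 16 choroid plexus markers. The fit without control replicate 1 therefore compares TCQA with a control array high in these markers. For them it cannot tell which control array stood apart. Of the 20 meningeal genes 9 were higher and 11 lower without control replicate 1. Ogn, Slc6a13, Slc6a20a and Mgp were then 1.22, 0.66, 0.60 and 0.43 higher, while Dcn, Fmod and Igf2 differed by -0.58, -0.27 and -0.23. Ogn, Slc6a13, Slc6a20a and Mgp had the smallest p of the list and non-overlapping arrays, so leaving out 1 array could not reverse them. A difference by treatment is not excluded for them, but these values cannot test it.

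The 4 arrays can be divided into pairs in 3 ways, too few for a share under 0.05. The real division gave 83 probe sets past the depositors' criterion and the highest other 86, and 2 of 3 gave at least 83. It gave 4 lists past camera and the highest other 10, so 2 of 3 gave at least 4. The interferon list passed in all 3 divisions, with a camera adjusted p of 8.61e-05 and 2.32e-05 in the others. The immediate early and meningeal lists were among the 10. The disease-associated microglia and reactive astrocyte list passed in the real division only. For the adjusted threshold the real division and the highest other both gave 0 with limma, which carries no information since any division gives at least 0, with 1386 probe sets at an unadjusted p under 0.05 in the real division and 1115 and 906 in the others. The division with 86 probe sets and 10 lists set both arrays numbered 1 against both numbered 2.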
